A study of Homo sapiens with 4 samples.

How the data were processed

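Gene expression was measured in 4 cultures of the HCC827 lung adenocarcinoma lineage, HCC827, HCC827GR, HCC827GR+ and HCC827GR.M6, with 1 array each. Groups were taken from the sample titles. Per the labels' protocols, total RNA was purified with an RNeasy kit, amplified and labelled with Cy3 by in vitro transcription. Per the file headers, each array was read with Agilent Feature Extraction 10.5.1.1 as a 1-colour scan of design 072363, whose probe coordinates are on hg19 (GRCh37), and all 4 arrays were on 1 slide and scanned on 1 day. The deposited values are spot intensity on a linear scale. Per the file headers, the processed intensity had a fitted spatial background subtracted, with a surrogate value for spots at background, and multiplicative detrending was applied on HCC827 and HCC827GR only. Further processing by the authors is not given in the sources used here.

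Each array held 60901 non-control spots of 58201 probes and 308 negative-control spots. Well above background were 41017 spots on HCC827, 52461 on HCC827GR, 50346 on HCC827GR+ and 53372 on HCC827GR.M6. No spot was saturated. The 75th percentile of the processed intensity was 544, 769, 753 and 641 in that order. The background used was 42.3 intensity units on HCC827 and 34.3, 34.3 and 33.8 on the others, and the mean of the negative controls after subtraction was outside the scanner software's range on HCC827. The slope of the spiked-in controls was 0.875, 0.857, 0.865 and 0.859 and outside that range on all 4 arrays.

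The value table deposited by the authors holds 37682 of the probes. Its columns were set against the scanner values of each array: all 37392 probes spotted once equalled the processed intensity within a relative 0.0001, so it is linear, not centred and in the same direction. Its column medians were 237, 343, 328 and 302 for HCC827, HCC827GR, HCC827GR+ and HCC827GR.M6. The rule by which its probes were chosen is not given in the sources used here, and it was used as an alternative only.

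The main value of a probe was log2 of its processed intensity minus the array's 75th percentile of it, after leaving out control spots and outlier flags and averaging spots of 1 probe. Probes were named through the reference gene table (GRCh38.p14, used for names only) by accession for 31104 probes, by symbol for 3366 and by older symbol for 496, and 23235 were unmatched and left out of gene results. A gene took the value and background flag of its probe with the highest mean over the 4 arrays, a probe counting as well above background when a share of at least 0.5 of its spots did, and 8201 of 23556 genes had more than 1 probe. The restriction to matched probes was decided after the files were seen and before any gene was counted. Which exon a probe lies in was not analysed here.

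No test, SE or p-value was computed, since each group has 1 array. For each of the 6 pairs of arrays a log2 difference was taken, and genes were counted at 2-fold and 4-fold. Where a gene was not well above background on 1 of the arrays, that array was set to the higher of the gene's own value and the lowest value of any probe well above background on that array, which makes the fold a bound, written as "at least". Genes not well above background on both arrays were left out. A bound under 1 was given no value. That last rule replaced an earlier handling after its counts had been seen, and the earlier handling is kept as an alternative.

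The 33 gene lists were fixed before the data were examined, and 31 of them are described one by one: epithelial, mesenchymal, EMT transcription factors, neuroendocrine effectors, neuroendocrine transcription factors, neuronal structure, lung lineage, squamous, ERBB, alternative receptor kinases, MAPK output, proliferation, stem-like, TGF-beta, interferon-stimulated, antigen presentation, NF-kB, hypoxia, YAP and TAZ, Notch, Wnt, drug metabolism, NRF2, BCL2, cholesterol, unfolded protein, cancer-testis, leukocyte, endothelial, hepatocyte and intestinal, and reference genes. The median log2 difference of a list's measured members was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. This rank describes these arrays and is not a p-value. A list was read as standing apart outside the 2.5 and 97.5 percentiles. With 198 such ranks computed, some fall outside by chance. The genes named, also fixed beforehand, were per comparison the 10 highest and 10 lowest, well above background and unsaturated on the brighter array and with all measured probes going the same way, leaving out uncharacterised, antisense, divergent, intronic and small RNA names, Y-linked genes and X-inactivation transcripts, up to 4 members of each list with the largest difference, 24 key genes on every array, and up to 8 genes per array and direction that differed at least 4-fold from each other array. Further members of lists and genes named beyond this rule were chosen for the text after their values were seen. Some of the genes that met this rule, 2 of the key genes and the other 2 lists are not reported here.

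Technical spread came from 300 probes spotted 10 times on each array. The median SD between spots of 1 probe was 0.057, 0.063, 0.061 and 0.030 log2 units on HCC827, HCC827GR, HCC827GR+ and HCC827GR.M6. It leaves out the spread between cultures, labellings and hybridisations. The number of arrays limits the precision.

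The procedure was tested on simulated data. For the fold counts and the random lists, every simulated array took its gene levels, spot-to-spot noise and detection limit from HCC827GR. The higher background of HCC827 and any spread between cultures or hybridisations were thus not simulated. These results check the calculation and not the error of the real arrays. For HCC827GR+ against HCC827, with 200 of 21639 genes changed, 95% of 3-fold and 94% of 8-fold changes passed 2-fold, 0% and 88% passed 4-fold, and 0 of 21439 unchanged genes passed 2-fold. For HCC827GR.M6 against HCC827, 3 of 100 random lists fell outside the limits. Correlations between 2 sublines' differences were set beside 100 simulations of unchanged sublines against the shared HCC827 array.

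The alternatives tried were quantile normalization, median scaling over probes detected on all 4 arrays, normexp background with an offset of 50 on the raw mean and local background intensity, no floor, detection on both arrays, no background filter, the mean over a gene's probes, the authors' value table, random lists without matching, and correlations over genes well above background on all 4 arrays. A background from the mean of the negative controls, with their SD as the lowest value (34.1 on HCC827GR+, where a few spots raised it), undoing the multiplicative detrending and keeping bounds under 1 were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 (for normexp) were used.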

Results

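Total RNA from 4 cultures of 1 human lung cancer lineage was measured on 1-colour oligonucleotide arrays, with 1 array for each culture. HCC827 is an established lung adenocarcinoma line that carries a deletion in exon 19 of EGFR, the receptor kinase that gefitinib inhibits, and it was grown drug-free. HCC827GR was derived from it by stepwise exposure to gefitinib and limiting dilution, and the submitters describe its resistance as unstable in drug-free passages. The other sublines are HCC827GR kept for more than 6 months at 1 µM gefitinib, called HCC827GR+, and HCC827GR kept for more than 6 months drug-free, called HCC827GR.M6. The labels call all 3 sublines resistant, and the growth protocol does not give the medium of HCC827GR itself. Of 60901 non-control spots, 67.4% were well above background on HCC827, 86.1% on HCC827GR, 82.7% on HCC827GR+ and 87.6% on HCC827GR.M6. The negative controls of HCC827 had a mean of -11.9 intensity units after background subtraction, against -4.64, -5.78 and -4.22 on the other arrays. The number of arrays limits the precision. With 1 array per group no difference has a replicate check, and every difference below describes these arrays. The only error available was technical. Combined from the spots of 1 probe within each of 2 arrays, the median SD of a single-spot log2 difference was 0.068 to 0.092. It leaves out the spread between labellings, hybridisations and cultures. Probes of 1 gene differed by a median SD of 0.16 to 0.24.

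The first comparisons set each resistant subline against HCC827, to describe what differs after resistance was acquired. Genes of epithelial cells were far lower on all 3 sublines. Far higher were genes such as IGFBP7 and ALDH1A1, whose brightest probes were not well above background on HCC827. MAL2, which takes part in transcytosis in polarised epithelia (brightest probe at chr8:120257557-120257616, hg19), was 403-fold lower on HCC827GR and 867-fold lower on HCC827GR+. On HCC827GR.M6 it was not among the 10 named genes with the lowest difference. The transcriptional repressor OVOL1 was 196-fold lower on HCC827GR, at least 205-fold lower on HCC827GR+ and 175-fold lower on HCC827GR.M6. CDH1, which encodes E-cadherin (chr16:68869214-68869273), had log2 differences of -6.07, -6.88 and -7.45 in that order, the last a 175-fold lower signal. CDH1 lies among neighbouring genes that were also lower, with a median log2 difference of -0.63 over a window of 20 genes. SFTA2, a surfactant-associated gene (chr6:30899485-30899544), was 266-fold, 413-fold and 291-fold lower, and ERP27 was 268-fold, 240-fold and 204-fold lower. PLAC8, ADGRF1, CSRNP2, CST6, RAB25, GALNT3, KLK6, SMIM22, BSPRY and MARVELD3 were also among the 10 named genes with the lowest difference on at least 1 subline.

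In the other direction, the brightest probe of IGFBP7, a secreted protein that binds insulin-like growth factors (chr4:57906990-57907049), was at least 1218-fold higher on HCC827GR, at least 1372-fold higher on HCC827GR+ and at least 815-fold higher on HCC827GR.M6. ALDH1A1, a retinaldehyde dehydrogenase (chr9:75516136-75516195), was at least 567-fold, 925-fold and 1045-fold higher by its brightest probe. The probes of both genes disagreed in size: the lowest log2 difference of a probe was 4.87, 4.92 and 4.34 for IGFBP7 and 2.20, 2.91 and 2.95 for ALDH1A1. The other of the 2 ALDH1A1 probes was well above background on HCC827, so the bounds for ALDH1A1 hold for its brightest probe only. The tight junction gene CLDN2 (chrX:106174032-106174091) was 440-fold, 138-fold and 1125-fold higher. TNFAIP6, an inflammation-induced hyaluronan-binding protein, was at least 368-fold higher on HCC827GR, at least 225-fold higher on HCC827GR+ and at least 85.6-fold higher on HCC827GR.M6. IL13RA2, CXCL6 and NRK were also among the 10 highest on HCC827GR and HCC827GR+, and AKR1C1, SERPINB3 and SERPINB4 on HCC827GR. PTPRD and ALPK2 were among them on HCC827GR+, and SLC4A4 on HCC827GR+ and HCC827GR.M6. VCAM1, PCSK5, GSTA2, GSTA5, LGALS2 and NR1H4 were among them on HCC827GR.M6. By their brightest probes PTPRD, SLC4A4, NRK and VCAM1 were at least 74.5-fold, 56.5-fold, 49.0-fold and 41.9-fold higher on all 3 sublines. Values of AKR1C1, of GSTA2 with GSTA5 and of SERPINB3 with SERPINB4 are uncertain, because near-identical relatives can bind the same probes.

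At least a 2-fold difference from HCC827 was seen for 1447 genes higher and 1055 lower among 20019 on HCC827GR, for 1253 higher and 1173 lower among 19830 on HCC827GR+, and for 1530 higher and 1331 lower among 20414 on HCC827GR.M6. At 4-fold the counts were 383 higher and 329 lower, 310 higher and 337 lower, and 308 higher and 404 lower. With normexp correction of the raw intensity and an offset of 50, changed together, the 2-fold higher counts were 892, 789 and 706, and 28 of the 32 counts of genes given here, over all comparisons, were more than 1.5 times lower, against 2 moved by that much with the background taken from the negative controls. On HCC827GR.M6 53.5% of the 2-fold genes were higher, and 46.4% after quantile normalization and 47.2% after median scaling. Other settings raised this share, to 67.1% with no floor and 62.0% with the authors' value table. With no background filter 44.0%, 35.3% and 43.2% were higher on the 3 sublines. Against HCC827, 151 genes were at least 4-fold higher and 225 at least 4-fold lower on all 3 sublines, out of 19587 compared. The 3 genes at least 4-fold from HCC827 in opposite directions on different sublines, named after their values were seen, were CXCL1, at 2.45 on HCC827GR and -3.84 on HCC827GR.M6, CSGALNACT1, at 3.03 and -2.60, and SAA1, at 2.14 and -2.06, which the near-identical SAA2 makes uncertain.

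The epithelial adhesion and differentiation list was lower on every subline. All 31 members were measured, and 26 on HCC827GR, 25 on HCC827GR+ and 25 on HCC827GR.M6 were at least 2-fold lower. The median log2 differences were -2.39, -2.24 and -2.28, each below all 10000 random lists matched on expression. EPCAM, an epithelial adhesion molecule, differed by -4.74, -4.11 and -4.93, and the splicing regulator ESRP1 by -3.52, -3.63 and -3.61. KRT8, a keratin of simple epithelia, differed by -2.13 and -2.16 on HCC827GR and HCC827GR+ and by -0.59 on HCC827GR.M6.

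The mesenchymal and extracellular matrix list had medians of 0.41 on HCC827GR, above 9993 of 10000 matched random lists, 0.21 on HCC827GR+, above 9805, and 0.01 on HCC827GR.M6, above 2725. Of its measured members, 6 of 25, 4 of 26 and 1 of 26 were at least 2-fold higher. With normexp background the HCC827GR+ median was -0.06. VIM, the intermediate filament of mesenchymal cells, was higher on all 3 sublines, by 3.66, 3.88 and 3.30. Fibronectin, FN1, differed by 1.87, 0.47 and -0.47, while COL1A1 differed by -2.11 on HCC827GR.M6. Of the EMT transcription factors, TCF4 was higher by 4.0, 4.05 and 3.35, ZEB1 by 2.40, 2.46 and 2.31 and ZEB2 by 2.74, 2.63 and 1.84, and SNAI1 was lower, at -1.86, -1.90 and -1.36. The medians of that list, 0.19, 0.04 and 0.38, lay above 8640, 5544 and 9611 random lists, and the last was -0.21 with no filter on background. ZEB2 and FN1 lie on chromosome 2, where 61 windows of 20 neighbouring genes had a median difference of -0.31 on HCC827GR.M6.

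The title of the study names a neuroendocrine small cell state, so neuroendocrine genes were looked at on each array. The neuroendocrine effector list had medians of 0.24, -0.07 and 0.62, above 9346, 2487 and 9991 of 10000 random lists. On HCC827GR.M6, 6 of 18 measured members were at least 2-fold higher and 3 at least 2-fold lower. A further 4 members had a bound under 1 there and were given no value, and keeping such bounds gave a median of 0.36. With normexp background the medians on the sublines were -0.05, -0.22 and 0.17. CPE, a peptide-processing enzyme, was higher by 2.17, 3.08 and 1.56, and SCG5, a secretory granule protein, by at least 3.40 and 4.33 on HCC827GR and HCC827GR+. On HCC827GR.M6, UCHL1, a ubiquitin hydrolase abundant in neurons, was higher by at least 1.60 and ENO2, the neuronal enolase, by 1.48, and RIMS2, a synaptic protein, differed by -4.07. CHGA and SYP, the vesicle proteins chromogranin A and synaptophysin, had scaled log2 signals of only -4.47 and -5.32 on HCC827, not well above background there, and -4.48 and -4.75 on HCC827GR.M6. The brightest probe of NCAM1, a neural adhesion molecule, was well above background on HCC827GR+ at -2.07 and on HCC827GR at -4.02, and not on HCC827 or HCC827GR.M6.

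The list of neuroendocrine transcription factors and small cell subtype genes had medians of 0.13, 0.04 and 0.21, above 7654, 5592 and 7287 random lists, and of -0.06, -0.15 and -0.10 with normexp background. POU2F3, the factor of tuft-like cells, had scaled log2 signals of -2.17, -2.46, -2.68 and -2.39 on HCC827, HCC827GR, HCC827GR+ and HCC827GR.M6. NEUROD1 was well above background only on HCC827GR, at -4.58, and INSM1 only on HCC827GR, at -4.77, and HCC827GR+, at -3.52. On HCC827, where a spot needed a higher signal to pass, NEUROD1 was at -5.83 and INSM1 at -4.14, so the flags alone show no gain. SOX2 was at -4.46 on HCC827, not well above background, and at -2.93, -4.11 and -3.67 on the sublines. The Notch ligand DLL3 was higher by 1.65, 2.31 and 2.19, and ONECUT2 by 1.98 on HCC827GR.M6. RB1 differed by -0.26, -0.13 and -0.19. The neuronal structure list, with medians of -0.05, 0.09 and 0.26, lay above 3451, 7540 and 7645 random lists, and DPYSL3 in it was higher by 2.57, 1.71 and 1.86.

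**Figure D1:**
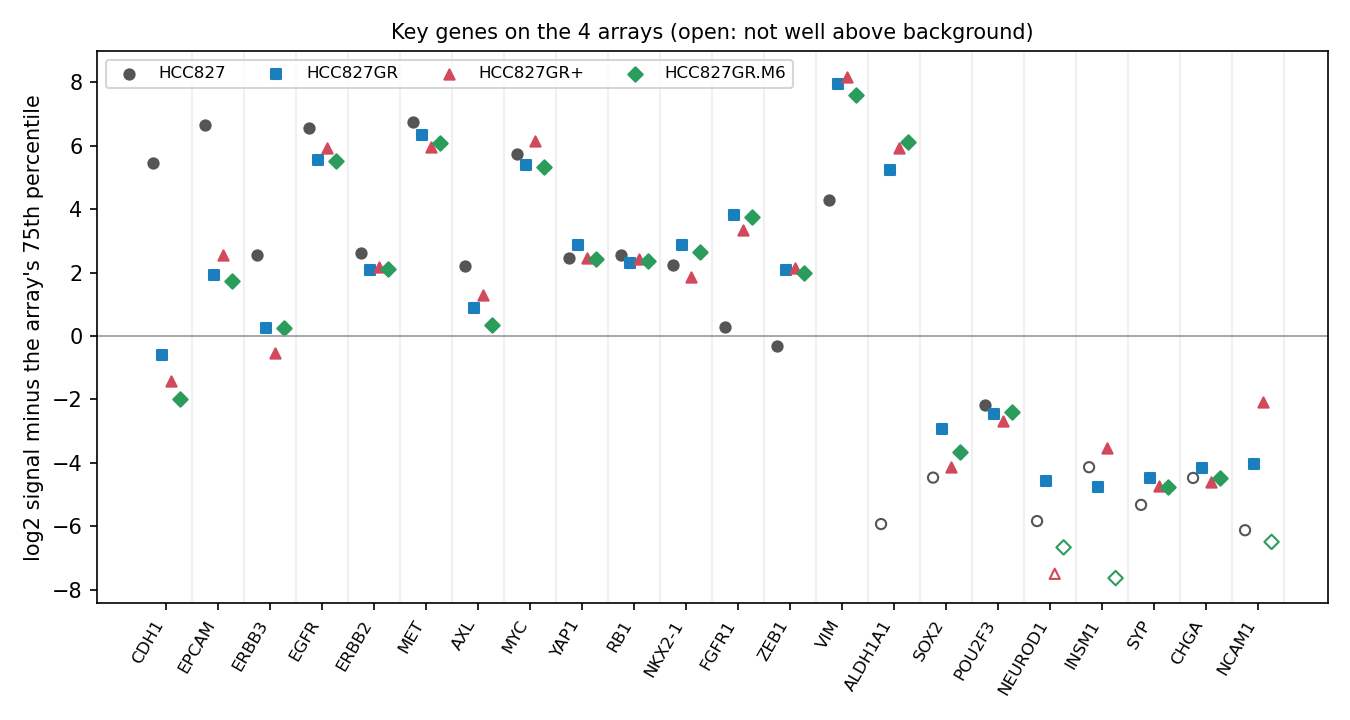
Scaled log2 signal (log2 signal minus the array's 75th percentile, vertical axis) of 22 key genes on the 4 arrays, 1 point per array, with open points for signals not well above background. CDH1 goes from 5.46 on HCC827 to -0.61, -1.42 and -1.99 on HCC827GR, HCC827GR+ and HCC827GR.M6, while POU2F3 stays between -2.68 and -2.17.

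Among receptor genes, EGFR was lower by log2 differences of -1.0, -0.63 and -1.02 on HCC827GR, HCC827GR+ and HCC827GR.M6, and 3 detected genes on each side of it had a median of -0.41. ERBB3, a partner of EGFR, differed by -2.30, -3.08 and -2.29, and AREG, a ligand of EGFR, by -2.02, -4.59 and -1.61. The ERBB receptor and ligand list had medians of -0.33, -0.45 and -0.50, above only 355, 27 and 31 of 10000 random lists. ERBB2 differed by -0.55, -0.45 and -0.50, MET by -0.39, -0.79 and -0.67 and AXL by -1.32, -0.90 and -1.86. FGFR1 was higher by 3.52, 3.05 and 3.49, and IGF2, whose probe may also read INS-IGF2 transcripts, by 6.53 and 3.26 on HCC827GR and HCC827GR+ and not on HCC827GR.M6, at -0.20. The list of alternative receptor kinases and ligands had medians of -0.18, -0.13 and -0.10, above 729, 1278 and 740 random lists.

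MAPK pathway output had a median of 0.53 on HCC827GR, above 9997 of 10000 random lists, -0.31 on HCC827GR+, above only 116, and 0.39 on HCC827GR.M6, above 9969. DUSP6, a phosphatase induced by ERK, differed by 1.43, -1.90 and 1.56. The NF-kB and inflammatory cytokine list had medians of 2.01 and 0.90 on HCC827GR and HCC827GR+, both above all 10000 random lists, and -0.27 on HCC827GR.M6, above 199. At least 2-fold higher were 23 of 26 members on HCC827GR, 12 of 26 on HCC827GR+ and 3 of 25 on HCC827GR.M6, where 9 were at least 2-fold lower. The chemokine CXCL8 differed by 4.18, 2.86 and -0.27, and the cytokine IL6 by 3.87, 2.94 and -1.29. TGF-beta family signalling had medians of 0.54, 0.41 and 0.29, above 10000, 9995 and 9717 random lists, with 7 members at least 2-fold higher on each subline and 3, 5 and 4 at least 2-fold lower. At 4-fold 1, 0 and 0 were higher and 2, 4 and 3 lower, among them INHBB at -4.17, -2.79 and -3.32. YAP and TAZ targets had medians of 0.16, 0.62 and -0.06, above 9705, 10000 and 4546 random lists.

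Cholesterol synthesis was lower on all 3 sublines, with medians of -1.07, -0.82 and -0.99, each below all random lists, and 12, 7 and 10 of 20 members at least 2-fold lower. INSIG1, a feedback regulator of the pathway, differed by -1.98, -1.57 and -1.93. Hypoxia and glycolysis genes had medians of -0.43, -0.51 and -0.41, above 65, 2 and 38 random lists, and EGLN3, an oxygen-sensing hydroxylase, differed by -2.49, -2.91 and -2.45. NRF2 targets, at -0.50, -0.40 and -0.66, lay above 7, 26 and 0 random lists, and NQO1 among them, in a window of neighbouring genes with a median of -0.73, differed by -1.21, -1.95 and -2.33. The unfolded protein and amino acid stress list had medians of -0.64, -0.40 and -0.37, above 0, 59 and 296 random lists. Proliferation genes had medians of -0.35, -0.50 and -0.41, above 393, 0 and 85 random lists, with 2, 2 and 0 of 27 members at least 2-fold lower. The reference genes also had negative medians, -0.27, -0.18 and -0.23, which lay above 5893, 4489 and 2928 of the lists matched on their bright expression. Wnt pathway genes, at -0.28, -0.23 and -0.18, lay above 39, 337 and 60 random lists, with FZD7 at -1.26, -1.41 and -3.00.

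Other lists stood apart on 1 or 2 sublines or on none, as did some of those above. Lung adenocarcinoma and alveolar lineage genes had medians of -0.09, -0.20 and 0.40, above 2909, 525 and 9980 random lists. In that list MUC1, a surface mucin, differed by -5.44, -5.71 and -3.67 and ABCA3, a lipid transporter of alveolar cells, by 4.11, 4.90 and 4.35. Antigen presentation genes had medians of 0.06, 0.13 and 0.38, above 9594, 9682 and 9999 random lists, with the peptidase ERAP1 at 1.48, 1.63 and 1.34. Interferon-stimulated genes had medians of 0.08, 0.05 and 0.19, above 8605, 7019 and 9583. Hepatocyte and intestinal markers had medians of 0.73, 0.04 and 0.65, above 9996, 5352 and 9980 random lists. Leukocyte markers, at -0.18, -0.21 and 0.13, and endothelial markers, at 0.21, 0.12 and 0.28, stayed between 590 and 7656 random lists.

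The stem-like and drug tolerance list had medians of 0.00, -0.07 and 0.02, above 6129, 3845 and 4778 random lists, with ALDH1A1 as its most different member, and CD44, a hyaluronan receptor, was higher by 1.59, 2.10 and 2.14. Drug efflux and metabolism genes, at 0.06, 0.20 and 0.20, lay above 8047, 9324 and 9506 random lists, with the transporter ABCC3 at 2.18 and 1.80 on HCC827GR and HCC827GR+ and UGT1A6, whose exons are shared with related genes, at 3.10, 1.97 and 2.17. Squamous and basal keratinocyte genes, at -0.04, -0.10 and 0.26, lay above 1568, 2063 and 7781 random lists. Notch pathway genes, at 0.07, 0.10 and 0.17, lay above 7190, 7831 and 8352, although NOTCH3 differed by -3.57, -4.39 and -4.04 and HEY1 by 2.31, 2.20 and 2.93. The BCL2 family had medians of 0.01, 0.05 and -0.16, above 6951, 6575 and 2659 random lists, and BCL2 itself was higher by 1.53, 1.49 and 1.61. Cancer-testis antigens had medians of -0.19, -0.20 and 0.16, above 1514, 1476 and 6718 random lists, with MAGEB2 at 3.77, 3.68 and 3.51. Mean and median had opposite signs for the TGF-beta list on HCC827GR+ and HCC827GR.M6, with means of -0.04 and -0.13. The same held for neuroendocrine effectors on HCC827GR+, with a mean of 0.20, for neuronal structure on HCC827GR and HCC827GR+, at 0.18 and -0.02, and for stem-like genes on HCC827GR+, at 0.38. It also held for alternative receptor kinases and cancer-testis antigens on HCC827GR, at 0.15 and 0.16, and on HCC827GR+, at 0.07 and 0.09, and for leukocyte markers on HCC827GR.M6, at -0.10.

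**Figure D2:**
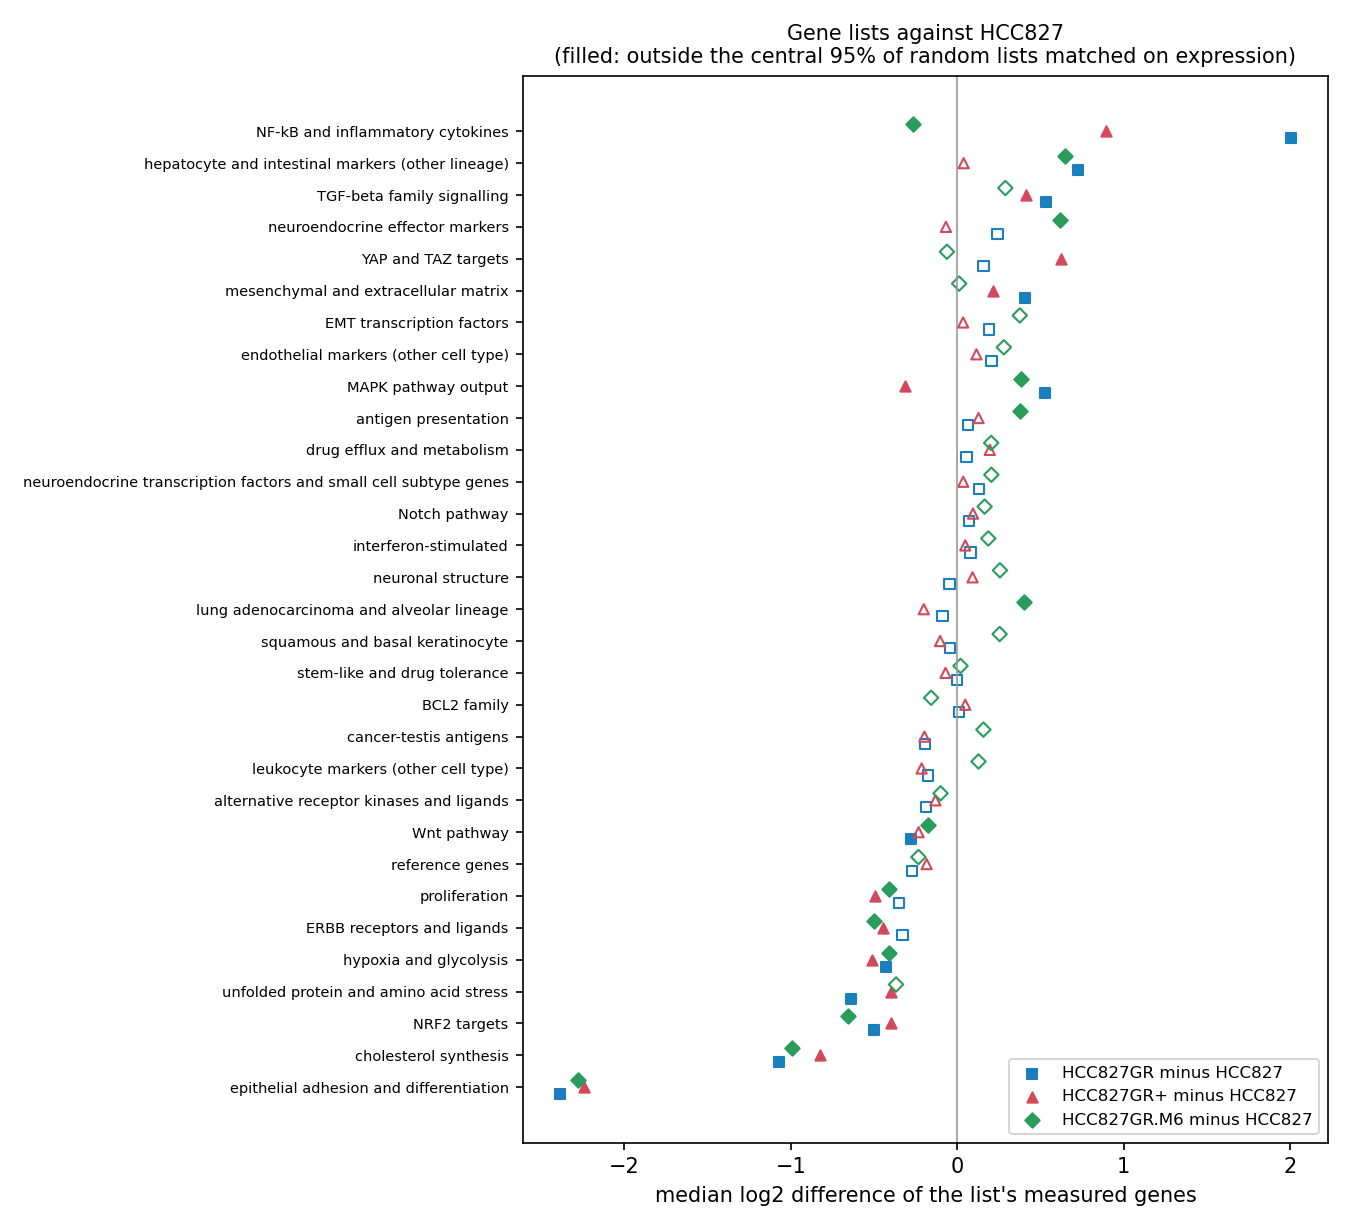
Median log2 difference from HCC827 (horizontal axis) of the measured members of 31 gene lists, 1 point for each of the 3 sublines, filled where the median lies outside the central 95% of 10000 random lists matched on expression. The epithelial list is lowest at -2.39, -2.24 and -2.28, and the NF-kB list spans 2.01, 0.90 and -0.27 on HCC827GR, HCC827GR+ and HCC827GR.M6.

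HCC827GR+ was compared with HCC827GR, its source, to describe what differs after long culture with the drug. Genes of inflammation and of MAPK output were lower on HCC827GR+. PTGS2, the inducible cyclooxygenase (chr1:186641469-186641528), was 18.0-fold lower, SPINK4 at least 46.9-fold, the fatty acid binding protein FABP1 at least 26.0-fold, CHI3L2 25.4-fold and HOXD4 at least 16.1-fold lower. SERPINB3 and SERPINB4 differed by log2 -4.58 and -4.46. The NF-kB list had a median of -1.16, with 14 of 26 members at least 2-fold lower, and MAPK output had -0.70, with 7 of 20, and both lay below all random lists. So did the smaller medians of TGF-beta signalling, -0.28, and proliferation, -0.17. Drug efflux and metabolism at -0.17, interferon-stimulated genes at -0.14 and hypoxia and glycolysis at -0.12 lay above 32, 21 and 40. DUSP6 differed by -3.33, ETV5, an ETS factor downstream of ERK, by -2.20 and EGR1 by -2.98. YAP and TAZ targets at 0.43 and cholesterol synthesis at 0.40 lay above all 10000 random lists, with ANKRD1 5.64-fold higher, and the epithelial list at 0.13 lay above 9781, although its mean was -0.06 and 0 of 30 members were at least 2-fold higher and 3 lower. S100G, CRCT1, FLI1, ENPEP and EDN2 were higher, at least 12.2-fold, 11.8-fold, at least 11.6-fold, at least 11.4-fold and 8.08-fold. In all, 241 genes were at least 2-fold higher and 600 lower among 21798, and 44 and 102 at 4-fold.

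HCC827GR.M6 was compared with HCC827GR to describe what differs after long culture without the drug. Inflammatory genes were again lower, by more than on HCC827GR+. PTGS2 was 178-fold lower, IGF2 106-fold, the chemokine CXCL1 78.4-fold, the phospholipase PLA2G4A 60.8-fold, CXCL6 59.3-fold, IL6 35.6-fold and PLEK 33.8-fold lower by their brightest probes, while another probe gave log2 differences of only -2.03 for IGF2, -2.63 for IL6 and -4.80 for CXCL1. The NF-kB list had a median of -3.02, below all random lists, with 21 of 26 members at least 2-fold lower. PCSK5, a proprotein convertase (chr9:78808212-78808271), was at least 313-fold higher by its brightest probe, with a log2 difference of 6.16 by its other probe. The chemokine CXCL14 (chr5:134907494-134907553) was at least 143-fold higher, the extracellular sulfatase SULF2 (chr20:46286424-46286483) 78.9-fold, LIMCH1 44.4-fold and angiotensinogen, AGT, 34.6-fold higher. The mesenchymal list had a median of -0.19, above 26 random lists, with FN1 at -2.34, and antigen presentation had 0.38, above 9999. MAPK output had a median of 0.06, above 5778, and a mean of -0.13. Unfolded protein and amino acid stress at -0.27, NRF2 targets at -0.24 and TGF-beta at -0.18 lay above only 80, 57 and 47 random lists, and the last turned to 0.01 with detection on both arrays. In all, 721 genes were at least 2-fold higher and 866 lower among 22187, and 80 and 176 at 4-fold.

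HCC827GR.M6 and HCC827GR+ both come from HCC827GR and were both kept for more than 6 months, without and with the drug. MAPK output was higher on HCC827GR.M6 and NF-kB genes were lower. The MAPK list had a median of 0.67, above all 10000 random lists, with 7 of 20 members at least 2-fold higher, among them DUSP6 at 3.46, EGR1 at 3.18, in a window of neighbouring genes with a median of 0.49, and ETV5 at 2.34. AREG differed by 2.98. The NF-kB list had a median of -1.94, below all random lists, with 19 of 26 members at least 2-fold lower, among them CXCL8 at -3.13, and IL6 was 18.7-fold and CXCL1 19.7-fold lower. YAP and TAZ targets at -0.58 lay below all random lists, the mesenchymal list at -0.28 above 1 and the BCL2 family at -0.47 above 6, with BMF, a BH3-only protein, at -2.19. Antigen presentation at 0.35 lay above all random lists and proliferation at 0.18 above 9993. EMT transcription factors at -0.40 and cholesterol synthesis at -0.28 lay above 96 and 200, and hepatocyte and intestinal markers at 0.42 and drug efflux and metabolism at 0.20 above 9872 and 9844. The neuroendocrine effector list had a median of 0.28, above 9032 random lists, and that of neuroendocrine transcription factors 0.19, above 7339, with SCG5 lower by 3.49 log2 units and GRP at 1.58. The brightest probe of NCAM1 was lower by at least 3.24, although another of its 3 probes was well above background on HCC827GR.M6 and not on HCC827GR+. PCSK5 was 189-fold higher, CXCL14 at least 114-fold, SULF2 111-fold, AGT 34.0-fold and ANK3 17.0-fold higher. INHBA, a subunit of activin, was 44.9-fold lower, CADM1 24.8-fold and CALHM6 24.2-fold. These are folds of the brightest probe, and the probe with the smallest log2 difference gave -0.16 for CADM1, 0.88 for ANK3, -1.48 for IL6, -2.63 for CXCL1 and 5.15 for PCSK5. ANXA8L1, which has near-identical relatives, was 60.9-fold lower.

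At least 2-fold higher on HCC827GR.M6 than on HCC827GR+ were 1238 genes and lower were 730, among 22032. At 4-fold 230 were higher and 156 lower, a split of 59.6% higher that was 45.7% after quantile normalization and 51.0% after median scaling. At 2-fold the split was 62.9%, and 50.8% after quantile normalization.

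Genes at least 4-fold apart from each of the other 3 arrays were most frequent on HCC827, with 225 higher and 151 lower. On HCC827GR 31 were higher and 0 lower, led by SPINK4, with a smallest difference of at least 19.7-fold, PTGS2 at 18.0-fold and CHI3L2 at 15.9-fold. On HCC827GR+ 13 were higher, led by IQCF4P, at least 12.1-fold, and CRCT1 at 11.7-fold, and the 3 lower genes were EGR1 at 7.86-fold, AREG at 5.93-fold and MILR1 at 4.94-fold. On HCC827GR.M6 31 were higher, led by PCSK5, with a smallest log2 difference of at least 6.72 by its brightest probe, SULF2, at least 70.8-fold, and CXCL14, at least 48.0-fold. The other probe of PCSK5 differed by 4.39 from HCC827. On HCC827GR.M6 33 were lower, among them INHBA at 17.7-fold, CXCL1 at 14.3-fold and the Wnt antagonist DKK1 at 12.7-fold.

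Across genes, which are not independent replicates, the differences of 2 sublines from HCC827 correlated with r of 0.88 for HCC827GR and HCC827GR+, 0.79 for HCC827GR and HCC827GR.M6 and 0.76 for HCC827GR+ and HCC827GR.M6. Because these share the HCC827 array, unchanged sublines simulated against it gave r of 0.589, 0.700 and 0.627. The covariances were 0.653, 0.614 and 0.576, beside simulated covariances of 0.00814, 0.00818 and 0.00816 that hold only the spread between spots. At least 4-fold higher on both were 231, 197 and 170 genes, where independent lists would share 5.77, 5.51 and 4.45, and at least 4-fold lower 263, 257 and 255, where they would share 5.64, 6.70 and 6.91. The single HCC827 array cannot be split, so part of the excess may come from that shared array. HCC827GR+ and HCC827GR.M6 were also grown from HCC827GR, so the lists are not independent by design. Part of the excess may therefore come from shared descent, and the sublines do not count as separate observations of resistance. These overlaps cannot tell shared descent and the shared array apart.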

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

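All tests in this part were chosen after the medians they weigh had been seen. Lists that stood apart from matched random lists in opposite directions on 2 sublines were picked out, and none of these differences was itself tested, because each subline has 1 array.

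The MAPK output list was higher than on HCC827 on HCC827GR and HCC827GR.M6 and lower on HCC827GR+. Its median difference from HCC827 was 0.84 higher on HCC827GR and 0.70 higher on HCC827GR.M6 than on HCC827GR+. Handling at harvest can move immediate early genes, here EGR1, FOS, FOSL1, IER3 and MYC. Without them the median difference of HCC827GR.M6 from HCC827GR+ over 15 members was still 0.62, which argues against a shift of those genes alone. The members left also follow MAPK activity, so handling that changed this activity cannot be told apart. The presence of gefitinib in the medium of HCC827GR+ stays open as a hypothesis. It cannot be told apart from other differences between the 2 cultures, since the median of 0.67 rests on 1 array of each kind.

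The NF-kB and inflammatory cytokine list was higher than on HCC827 on HCC827GR and HCC827GR+ and lower on HCC827GR.M6. Its median difference from HCC827 was 2.27 higher on HCC827GR and 1.16 higher on HCC827GR+ than on HCC827GR.M6. Taken directly, the median difference of HCC827GR.M6 was -3.02 from HCC827GR and -1.94 from HCC827GR+. The background of faint genes is argued against by the 16 members with both signals in the upper part of detected genes, whose median difference of HCC827GR.M6 from HCC827GR+ was -2.07. Leukocytes among the HCC827GR+ cells would lower their markers on HCC827GR.M6. That list had a median of 0.27, with PTPRC at 0.23 and TYROBP at 0.23, although LAPTM5 was at -1.66. Markers such as CD79A, at 3.73, and PTPRC, at -0.06, were well above background on HCC827 too, while LAPTM5 was not. A small share of leukocytes could be hidden under such signal, so the list does not decide. Gefitinib in the medium stays open as an untested biological explanation and cannot be told apart from culture history, since the median of -1.94 rests on 1 array of each kind.

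Among 23225 probes without a matched gene, which the comparisons do not use, 15 were at least 4-fold higher than on HCC827 on all 3 sublines.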

How the results depend on the processing

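The negative-control background, the undone detrending and the kept bounds under 1 were chosen after seeing the data. So was the choice of lists given singly: the 5 closest to the study's title against HCC827, and MAPK output and NF-kB between HCC827GR.M6 and the other sublines, while all other lists are counted together. In each set below, values follow the order HCC827GR, HCC827GR+, HCC827GR.M6. The epithelial list stayed between -2.56 and -2.07, and MAPK output and NF-kB between HCC827GR.M6 and HCC827GR+ kept their direction, under every alternative. The mesenchymal list kept its direction on HCC827GR, and the neuroendocrine effectors on HCC827GR.M6, under every alternative. The other medians of those 2 lists, of EMT factors and of neuroendocrine transcription factors turned under at least 1, and the cause was not tested. Of all 33 lists and 6 comparisons, 1635 list medians moved by less than the spot-to-spot SD of a difference, 540 by more, and 3 that stood apart reversed. Of the named genes, 7263 values moved by less than that SD, 3176 by more, and 3 of at least 2-fold reversed. Without matching, 18 of 198 list ranks crossed a limit. Signal over background limits the faint genes: 28 of 32 counts moved under normexp, 10 with no floor, 4 with detection on both arrays, 3 with no filter and 2 under the negative-control background. Normexp changed the method, the intensity it starts from and an offset of 50 together, so its moves cannot be put down to the background alone. All 32 counts stayed within 1.5 times under quantile normalization, median scaling, the mean over probes, the authors' value table, the undone detrending and the kept bounds.

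With normexp background, genes at least 2-fold higher than on HCC827 were 892, 789 and 706, at least 4-fold higher 234, 182 and 181, at least 4-fold lower 212, 211 and 235, and at least 2-fold lower 771 on HCC827GR+. For HCC827GR+ against HCC827GR, 2-fold counts were 131 higher and 266 lower and 4-fold counts 12 and 53. For HCC827GR.M6 they were 249 and 550, and 32 and 96, against HCC827GR, and 537 and 481, and 62 and 75, against HCC827GR+. Genes at least 4-fold apart from each other array were 147 higher and 83 lower on HCC827, 19 higher on HCC827GR, 5 higher on HCC827GR+, and 17 higher and 14 lower on HCC827GR.M6. Epithelial medians were -2.21, -2.07 and -2.10, neuroendocrine effector medians -0.048, -0.22 and 0.17, and neuroendocrine transcription factor medians -0.062, -0.15 and -0.10. Mesenchymal medians were -0.057 on HCC827GR+, reversed from 0.21, and -0.18 on HCC827GR.M6, and EMT factor medians -0.021 and -0.093 on HCC827GR and HCC827GR+. Between HCC827GR.M6 and HCC827GR+ the NF-kB median was -1.72, and that of the Wnt list reversed from -0.19 to 0.044. Between HCC827GR.M6 and HCC827GR the NF-kB median was -2.91.

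With no floor for dim genes, 2236 and 2737 genes were at least 2-fold higher on HCC827GR and HCC827GR.M6 than on HCC827, and 559 at least 4-fold higher on HCC827GR.M6. At 4-fold, 157 were lower on HCC827GR+ than on HCC827GR, 124 higher on HCC827GR.M6 than on HCC827GR and 406 higher than on HCC827GR+. Genes apart from each other array were 1 lower on HCC827GR, 22 higher and 6 lower on HCC827GR+ and 59 higher on HCC827GR.M6. The neuroendocrine effector median was 0.35 on HCC827GR and that of EMT factors 0.91 on HCC827GR.M6. With no background filter, 1840, 2305 and 2009 genes were at least 2-fold lower than on HCC827. Mesenchymal medians were 0.27 on HCC827GR and -0.077 on HCC827GR.M6, where EMT factors had -0.21 and neuroendocrine effectors 0.36. With detection on both arrays, which leaves fewer genes, 29 genes were at least 4-fold higher on HCC827GR+ than on HCC827GR, and 15, 4 and 14 were higher than on each other array. Neuroendocrine effectors had 0.13, -0.20 and 0.45, the epithelial list -2.09 and -2.20 on HCC827GR+ and HCC827GR.M6, the mesenchymal list -0.077 and neuroendocrine transcription factors 0.14 on HCC827GR.M6. The TGF-beta list reversed from -0.18 to 0.015 for HCC827GR.M6 against HCC827GR. With bounds under 1 kept, neuroendocrine effectors had 0.037, -0.17 and 0.36, neuroendocrine transcription factors 0.017 on HCC827GR and EMT factors -0.21 on HCC827GR.M6.

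With the negative-control background, epithelial medians were -2.28 and -2.12 on HCC827GR and HCC827GR+, EMT factors 0.10 and -0.11, and neuroendocrine effectors 0.14, -0.17 and 0.48. Mesenchymal medians were 0.10 and -0.16 on HCC827GR+ and HCC827GR.M6, and neuroendocrine transcription factors had 0.057 on HCC827GR.M6. It gave 152 genes at least 4-fold higher on HCC827GR.M6 than on HCC827GR+, and 8 higher on HCC827GR+ than on each other array. The NF-kB median between HCC827GR.M6 and HCC827GR was -3.10 with this background and also with detrending undone. With detrending undone, epithelial medians were -2.30 and -2.15 on HCC827GR and HCC827GR+, EMT factors -0.064 and neuroendocrine effectors -0.17 on HCC827GR+, and the mesenchymal list -0.10 on HCC827GR.M6.

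With quantile normalization, epithelial medians were -2.17 and -2.08 on HCC827GR and HCC827GR+, neuroendocrine effectors 0.15 and 0.36 on HCC827GR and HCC827GR.M6, and neuroendocrine transcription factors 0.026 on HCC827GR.M6. MAPK output was then 0.75 for HCC827GR.M6 against HCC827GR+. On HCC827GR.M6 the epithelial, EMT factor, neuroendocrine effector and neuroendocrine transcription factor medians were -2.35, 0.31, 0.55 and 0.13 with median scaling, and -2.18, 0.47, 0.55 and 0.34 with the authors' value table. For HCC827GR.M6 against HCC827GR+, MAPK output was 0.58 and 0.77 and NF-kB -2.03 and -1.84 under these settings. With the mean over a gene's probes, epithelial medians were -2.54 and -2.56 on HCC827GR+ and HCC827GR.M6, and EMT factors had 0.52 and neuroendocrine effectors 0.77 on HCC827GR.M6. In that setting MAPK output was 0.86 for HCC827GR.M6 against HCC827GR+, and NF-kB was -3.19 for HCC827GR.M6 against HCC827GR. That setting reversed FLT1 from 1.13 to -0.068 and PECAM1 from 1.80 to -0.029, both for HCC827GR.M6 against HCC827GR+, and NRARP from 1.37 to -0.0096 against HCC827GR, since a fainter probe of each goes the other way. Correlations across genes were 0.87, 0.77 and 0.74 over genes well above background on all 4 arrays.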

Other observations

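Of the tests below, the choice of chromosomes 2, 3, 4, 5 and 16 was made only after the window results had been seen, and the dimming at each array's own flag level was added after the first dimming result.

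HCC827GR.M6 differed from HCC827GR+ in genes of the TGF-beta and Wnt lists, whose medians of -0.19 and -0.19 lay above only 58 and 13 of 10000 matched random lists, the Wnt median turning to 0.044 with normexp background. At least 2-fold lower were 3 of 23 and 5 of 21 members, and 3 and 1 were at least 2-fold higher. INHBA differed by -5.49, LTBP1, a latent TGF-beta binding protein, by -2.53 and TGFB2 by -2.26, while BMP4 differed by 3.43. Of the Wnt genes, the antagonist DKK1 differed by -3.67 and the target SP5 by -2.31, and the receptor FZD8 was higher by at least 3.04. ALDH1A3, a relative of ALDH1A1, differed by -2.04, and the stress-induced enzyme HMOX1 by -1.95.

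In the lung lineage list, with a median of 0.21 above 9564 random lists, 4 of 23 members were at least 2-fold higher on HCC827GR.M6 and 0 lower. NAPSA, an aspartic protease of alveolar cells, differed by 2.61 and MUC1 by 2.04 from HCC827GR+, SFTPD, a surfactant protein, by 1.69 and HOPX by 1.21. The epithelial genes KRT8 and MAL2 differed by 1.57 and 4.0, in a list whose median was -0.012. CDKN1C, an inhibitor of cyclin-dependent kinases, differed by 1.95, CDKN1A by 1.38 and the ERBB ligand NRG4 by 1.97. HLA-DMB, which loads peptides on class II molecules, differed by 1.72, and the interferon-stimulated genes IFITM1 and BST2 by 2.13 and 1.68, in a list whose median of 0.18 lay above 9869 random lists.

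Fewer spots were well above background on HCC827 than on the other arrays. With each array's mean negative control as background, 83.6% of HCC827 spots lay at least 15 units above it, beside 88.8% on HCC827GR, 85.5% on HCC827GR+ and 88.6% on HCC827GR.M6, a gap of 1.84 points to the lowest. A subtracted background that was too high on HCC827 is a candidate explanation. A dimmer array is argued against as the whole cause: HCC827GR.M6 dimmed to the 75th percentile of HCC827 still had 86.6% of its spots above that level. The scanner's flag is another measure, so the dimming was repeated at the level above the mean negative control that gives each array its flagged share, 41.0 units on HCC827 and 18.7, 18.9 and 16.3 on the others. Dimmed alike, HCC827GR, HCC827GR+ and HCC827GR.M6 kept 81.2%, 78.2% and 85.5% of spots at their own level, against 67.4% on HCC827. A part played by dimness stays open. No biological explanation was tested.

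A hypothesis that neighbouring genes share copy number or other regional differences was tested on 926 windows of 20 neighbouring detected genes, in hg19 probe order. For the mean of the 3 sublines against HCC827, 30 windows had a median of at least 0.4 either way, 24 lower and 6 higher, and the highest of 100 shuffles of gene order had 5. For HCC827GR.M6 against HCC827GR+ the count was also 30, with 24 lower and 6 higher, and the highest shuffle had 3. Copy number may lie behind such runs, and so may shared regulation of gene clusters, since windows of histone genes and of HOXA genes were among them, and no DNA was analysed here.

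On chromosome 16, 8 of the 18 windows from position 46736255 (hg19) to the end were at least 0.4 lower on the sublines, and 17 were below 0, with a median of -0.34, while the 22 windows before it had a median of -0.01 and none below -0.18. That position is the start of the first window at least 0.4 lower, so by this choice no window before it could be that low. CDH1 and ESRP2 lie in a window with a median of -0.63. On chromosome 3, 8 of 51 windows were at least 0.4 lower. Chromosome 2 was lower on HCC827GR.M6 over most of its length: 58 of 61 windows were below 0 against HCC827GR+, with a median of -0.30, all 61 against HCC827, with a median of -0.31, and 58 against HCC827GR, while for HCC827GR+ against HCC827GR the median was 0.00. Chromosome 4 was also lower on HCC827GR.M6 than on the other sublines, with 29 of 31 windows below 0 against HCC827GR+, 4 of them at least 0.4 lower, and 27 against HCC827GR, at medians of -0.26 and -0.20, and less so against HCC827, at -0.07. On chromosome 5, 10 of 41 windows were at least 0.4 higher on HCC827GR.M6 than on HCC827GR, and EGR1 lies in a window with a median of 0.49 against HCC827GR+.

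A hypothesis that the sublines hold fewer copies of the EGFR region was tested on the 3 nearest detected genes on each side of EGFR. Their median difference of -0.41, beside -0.88 for EGFR itself, lay at percentile 6.22 of 18631 such windows and decided neither way. SEC61G differed by -0.67 and VOPP1 by -0.19, while LANCL2, next to EGFR, differed by 1.09. EGFR-AS1 overlaps EGFR, so its -0.78 is not independent.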
